A study of Folsomia candida with 62 samples.

How the data were processed

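RNA was taken from pools of about 30 springtails (Folsomia candida, a soil arthropod used in soil toxicity tests), 23 days old, that had lived for 2 days in soil, per the labels. The soil was the standard soil LUFA 2.2, clean or spiked with barium, cadmium, cobalt, chromium, lead or zinc, or 1 of the field soils Noy and PLO. Each metal was given at an EC10 and an EC50 dose, the concentrations named for a 10% and a 50% effect. The 62 samples were hybridised in pairs, 1 per dye, on 31 2-colour Agilent arrays on 5 slides, in 2 exposure series that each had their own clean soil control. Series 1 held barium, cadmium, lead and zinc with 35 samples, and series 2 held cobalt, chromium and the field soils with 27 samples.

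Per the file headers, the scanner files hold the mean intensity of every spot and the median intensity of its local background in both channels, with no normalization, and a processed intensity that Feature Extraction 9.5.1.1 had background-subtracted, detrended and dye-normalized within each array. The file of each array was deposited under both of its samples, so the dye named in the labels gave the channel of each sample. The authors also deposited a table of log2 values, for which the submitters' processing notes name Feature Extraction and limma. The deposited log2 value column of each sample correlated better with the channel of its own dye than with the other channel in 62 of 62 samples, with the lowest Spearman's rho at 0.9986 across probes (probes are not independent replicates), and its medians lay between 8.014 and 8.0143. These values are 1-channel levels with higher meaning more RNA, and the centring that gave their common median is not stated.

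The mean intensities were read into limma 3.58.1 under R 4.3.3. Background was corrected with normexp on all spots with an offset of 50, the channels were normalized within arrays by loess with weight 0 for the 536 control spots and without spots that were non-uniform outliers, and then between arrays by Aquantile. The offset is added to every signal, so it draws the fold changes of dim genes toward 0. The 3 spots of a probe were averaged, and each of the 5069 genes had 1 probe, so no rule for several probes was needed. A gene was kept when its probe was well above background in at least 3 samples, which left 4401 genes, with 268 missing values in the table. Gene names are those of the array's annotation, which came from sequence similarity and also names genes of other organisms. Identifiers starting with Fcc are given with them, 2748 genes had no database match, and 910 of the kept genes had a usable name. The files give no genome positions, and no reference genome was at hand.

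Gene levels were fitted with limma over all 62 samples, with 16 groups, a dye term, the array as a random block (correlation 0.113) and a mean-dependent prior for the variance. Values are log2 fold changes with their standard errors (SE, written after ±) and p-values adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Groups had 4 samples, except that the zinc EC10 and Noy groups had 3. Where a probe was not well above background in any sample of a group, the fold is a lower bound against the lowest well-measured signal of those samples, written "at least". Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. The p-values were adjusted over all 238 tests, which were 17 lists in 14 comparisons. The lists were metal binding and transport, heat shock and chaperones, antioxidant enzymes, cytochrome P450, phase II conjugation, ABC transporters, digestive proteases, carbohydrate hydrolases, cuticle and chitin, immunity, beta-lactam synthesis, ribosome, proteasome and ubiquitin, mitochondrial respiration, lipid metabolism, DNA damage and apoptosis, egg yolk, muscle, nervous system, and bacterial genes. The digestive proteases and carbohydrate hydrolases served as gut markers, and the bacterial list as a marker of microbes in or on the animals. Lists with fewer than 5 kept genes were counted and not tested.

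Similarity of responses was measured across genes with Pearson's and Spearman's correlation and the covariance of log2 fold changes. Where comparisons shared a control, 100 simulations with no effect were run on that control, and the control was also split so that each comparison had its own control samples. In the simulations each gene varied independently of the others. They leave out variation that genes share in real samples, so correlations with no effect can spread more widely than simulated. A classifier of uncorrelated shrunken centroids was trained on the 43 samples labelled for training and applied to the 12 validation samples and the 7 field soil samples. There were 7 classes, the 6 metals and clean soil. Its shrinkage, from 0 to 10 in steps of 0.5, and its correlation threshold, from 0.7 to 1, were chosen by leaving out 1 array at a time. Its p-values are 1-sided and come from 100000 permutations of the class labels. One PLO sample labelled for training was left out of training, since field soil is not a class.

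Genes named in the text follow a fixed rule. For each metal at EC50, up to 8 named genes that rose and 8 that fell most were taken among those past the threshold whose every exposed sample lay on 1 side of the control mean, and at EC10 too where fewer than 3 passed at EC50. Where such a gene is said to move in 4 of 4 samples, this follows from the rule and is no further evidence. For the field soils and the controls the limit was 5 and 5, for differences among metals the 10 highest F statistics, for each list up to 4 members that passed, for the classifier up to 3 per class, and for genes with an identifier only at most 2 and 2. Where no gene passed, the 3 named genes of smallest p are given. The design, the comparisons, the lists, the naming rule and the alternatives were chosen before the data were examined. Chosen after were 4 alternatives for the lists (slide block, number block, no background correction, the deposited log2 values), the removal of clone names from the usable gene names, and the tests that the closing section names as such.

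Alternatives were the processed intensities with quantile normalization, no background correction, no filter on dim probes, the deposited log2 values, the slide as a fixed block, no dye term, the replicate number as a block, and each sample left out in turn. Samples of the same number did not deviate together, with a median r of -0.0173 across genes over 166 same-numbered pairs against 0.00326 over 690 others, and every pair lay above 0.1 in 1 of 22 comparisons, PLO against its control, where the number block called 21 genes against 22 without it and 2 lists against 1. The fit, the list tests, the similarity and the classifier were tested on simulated gene levels, with 200 changed genes per comparison for the fit. These took the series 1 control means and the spread of each gene from the real data, with errors independent between genes. Real genes vary together, with an estimated correlation of 0.248 in the ribosome list, so the recovery and false calls below can be too favourable. For chromium EC50 against its control, with 4401 genes tested, 50% of genes changed by 0.5 on the log2 scale were recovered, 92.8% of those changed by 1 and 98.4% of those changed by 2, with 10 false calls among 184. For Noy, with 3 samples, the shares were 37.1%, 73.4% and 95.5%, with 9 false calls among 145. A simulated fall by 0.4 of the 35 ribosome genes in chromium EC50 was recovered with an adjusted p of 3.15e-11 with the preset correlation, beside 1 of the 237 other tests; this size and group were set after a fall by 0.2 in cobalt EC10 was not recovered. In 10 draws each, falls by 0.4 and 0.3 were recovered in 10 of 10 in both groups, falls by 0.2 in 3 of 10 for chromium EC50 and 1 of 10 for cobalt EC10, and falls by 0.1 in 0 of 10. The classifier placed 12 of 12 simulated validation samples with 60 genes per metal raised by 1 and 2 of 12 with no effect. The median net signal of a sample lay between 85.8 and 701.8 intensity units, between 67.15% and 86.53% of its spots were well above background, and 0 spots were saturated. The number of arrays limits the precision.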

Results

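The data are the expression levels of 5069 genes of the springtail Folsomia candida in 62 samples from animals kept for 2 days in clean soil, in soil spiked with 1 of 6 metals, or in 1 of 2 field soils. The study asked whether the genes that respond can tell soils with different metals apart. There were 16 groups, 14 with 4 samples and 2 (zinc EC10 and Noy) with 3. Doses at EC10 and EC50 were 583.3 and 1159.3 mg/kg for barium, 27.7 and 41.2 for cadmium, 272.4 and 368.7 for cobalt, 29.3 and 43.5 for chromium, 540.1 and 1158.6 for lead, and 285.0 and 476.2 for zinc. The slides held 16, 6, 10, 16 and 14 samples and at most 2, 1, 2, 2 and 3 samples of a group, too few for values within a slide, so counts with the slide as a block are given beside the main counts. Over all comparisons and scalings the median log2 fold change of all genes differed from 0 by at most 0.0575. Each scaling brings the samples to a common level, so this value cannot show whether RNA levels shifted as a whole.

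At EC50 of barium, glutamate dehydrogenase (Fcc04585), which links glutamate to the citric acid cycle, rose 1.84-fold (log2 0.88 ± 0.14, adjusted p = 7.1e-05), and phosphoserine aminotransferase 1 (Fcc05461), a step of serine synthesis, rose 1.91-fold (0.93 ± 0.17, adjusted p = 0.000968), each in 4 of 4 samples. The protease inhibitor cystatin A2 (Fcc02429) rose by 0.41 ± 0.10 (adjusted p = 0.0383), and anterior fat body protein (Fcc04062) fell 1.97-fold (-0.98 ± 0.25, adjusted p = 0.0365). Among genes with no name, Fcc04512 rose 7.18-fold (2.84 ± 0.70) and Fcc06212 rose 4.42-fold (2.14 ± 0.39), while Fcc05623 fell 2.55-fold (-1.35 ± 0.25) and Fcc02992 fell by 1.27 on the log2 scale. In all, 37 of 4401 genes changed against the series 1 control in 4 against 4 samples, 29 up and 8 down, and 40 with the slide as a block. With the processed intensities the split was 22 up and 19 down, and with the deposited log2 values 22 up and 13 down. The count was 80 without barium EC50 replicate 1, 23 without replicate 2, 20 without replicate 3, 19 without control replicate 3 and 22 without control replicate 4. The call of cystatin A2 was lost with the slide block, the processed intensities and the deposited values, and that of anterior fat body protein with the slide block.

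At EC10 of barium, 2 genes rose, 2 also with the slide as a block, and both have an identifier only and were chosen after their values were seen. Fcc00369 rose by 1.19 ± 0.15 on the log2 scale (adjusted p = 8.27e-07) and by 0.91 ± 0.15 at EC50, and Fcc01977 rose by 1.09 ± 0.21 (adjusted p = 0.0082) and by 1.14 ± 0.21 at EC50. The count was 1 without barium EC10 replicate 1, without replicate 4 and without control replicate 3. From EC10 to EC50, 9 genes rose and 0 fell, among them Fcc04512 (9.66-fold, 3.27 ± 0.69, adjusted p = 0.0214) and Fcc06212 (3.36-fold, 1.75 ± 0.38, adjusted p = 0.0237). Both lost the call with the slide as a block, where 3 genes passed, and the count of 9 was 5 with the processed intensities. It was 1 without barium EC10 replicate 1, 2 without replicate 2, 3 without replicate 4, 5 without EC50 replicate 1, 2 without EC50 replicate 3 and 5 without EC50 replicate 5.

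Cadmium raised 1 gene strongly at both doses. Repressor protein (Fcc03748) rose 2.17-fold at EC10 (1.12 ± 0.12, adjusted p = 3.56e-09) and 2.16-fold at EC50 (1.11 ± 0.12, adjusted p = 3.88e-09), in 4 of 4 samples at each dose. It kept the call under every alternative and every left-out sample. At EC10, Fcc02517 rose 5.81-fold (2.54 ± 0.47, adjusted p = 0.00459) and Fcc00272 rose by 2.03 ± 0.42 on the log2 scale (adjusted p = 0.0144); both have no usable name. In all, 7 genes rose and 0 fell at EC10 (6 with the slide block), and 1 rose at EC50 (1 with the slide block). With the processed intensities 3 passed at EC10, and the calls of Fcc02517 and Fcc00272 were lost. The EC10 count was 14 without cadmium EC10 replicate 1, 2 without replicate 2 or 3, 4 without control replicate 1 or 4 and 3 without control replicate 3, and the EC50 count was 4 without cadmium EC50 replicate 5.

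Between the cadmium doses, limma called 0 genes, with 92 at an unadjusted p under 0.05 and 0 with the slide block. The named genes of smallest p were whey acidic protein core (Fcc01910) at 0.94 ± 0.27, neurofilament triplet H1-like protein (Fcc00505) at -0.17 ± 0.06 and the antioxidant enzyme Mn superoxide dismutase (Fcc03714) at -0.39, all with an adjusted p of 0.998. The count was 4 without cadmium EC10 replicate 1 and 3 without replicate 4.

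For lead, limma called 0 genes at EC10 (149 at an unadjusted p under 0.05), 0 at EC50 (374) and 0 between the doses (332). The named gene of smallest p at both doses was retinol dehydrogenase 12 (Fcc00270), a retinoid-converting enzyme, at 1.55 ± 0.41 at EC50 (adjusted p = 0.2) and 1.51 ± 0.41 at EC10 (adjusted p = 1). At EC50 tyramine receptor (Fcc02791) stood at 0.44 ± 0.12 and selenoprotein W1 (Fcc05153) at -0.66 ± 0.18, both with an adjusted p of 0.2. At EC10 prepro actinohivin (Fcc01646) stood at -2.03 ± 0.65 and esterase (Fcc05925) at -0.61 ± 0.20. Between the doses, licorne (Fcc04304) stood at -0.41 ± 0.11, putative protein disulfide isomerase (Fcc04354) at -0.66 ± 0.18 and fibrinogen C domain protein (Fcc00201) at 1.52 ± 0.42, all with an adjusted p of 0.428. The slide block called 0 genes at EC10, 1 at EC50 and 0 between the doses, and the processed intensities and the deposited values each called 1 at EC50. The EC50 count was 18 without lead EC50 replicate 5 and 1 without control replicate 1.

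Zinc at EC50 changed 3 genes, all with an identifier only. Fcc02520 rose 1.84-fold (0.88 ± 0.17, adjusted p = 0.0216), Fcc05212 rose 1.72-fold (0.79 ± 0.17, adjusted p = 0.048) and Fcc05623 fell 2.23-fold (-1.16 ± 0.25, adjusted p = 0.048). The slide block called 4 genes. With no background correction, no filter, no dye term, the number block or the deposited values 1 gene passed, and with the processed intensities 1 rose and 1 fell; in 6 of the 7 alternatives the call of Fcc05212 was lost, and in 5 that of Fcc05623. The count was 0 without zinc EC50 replicate 2 or 3 or control replicate 2 or 4, and 1 without zinc EC50 replicate 4. At EC10, in 3 against 4 samples, limma called 0 genes (214 at an unadjusted p under 0.05, 0 with the slide block), with 1 gene without the filter and 2 without zinc EC10 replicate 2. The named genes of smallest p there were electron carrier (Fcc05985), at least 1.82-fold higher, and 2 digestive enzymes, Trypsin I (Fcc00536) at -0.74 ± 0.22 and hepatopancreas trypsin (Fcc05730) at -0.59 ± 0.18, all with an adjusted p of 0.667. Between the doses 0 genes were called (127 at an unadjusted p under 0.05, 0 with the slide block, 2 without zinc EC10 replicate 3), and phosphoserine aminotransferase 1 (Fcc05461) stood at 0.56 ± 0.18, pancreatic lipase related protein (Fcc02519) at -0.68 ± 0.25 and an ABC transporter binding protein (Fcc05098) at 1.42 ± 0.54, all with an adjusted p of 0.999.

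Cobalt at EC50 raised retinol dehydrogenase 12 (Fcc00270) 4.79-fold (2.26 ± 0.41, adjusted p = 0.000487) and deleted in malignant brain tumors 1 (Fcc02291), a scavenger receptor protein of mucosal surfaces, 3.84-fold (1.94 ± 0.34, adjusted p = 0.000333). Hepatopancreas trypsin (Fcc05730), a digestive protease, fell 2.48-fold (-1.31 ± 0.16, adjusted p = 7.39e-07), putative protein disulfide isomerase (Fcc04354), which forms disulfide bonds in secreted proteins, fell by 1.05 on the log2 scale (adjusted p = 0.000307), and putative core protein (Fcc00928) fell 2.20-fold (-1.14 ± 0.25). Each moved the same way in 4 of 4 samples, as the naming rule requires. Fcc05730 and Fcc04354, and Fcc05623 below, fell in all 6 comparisons against the series 2 control. Fcc05730 was also 1.01 higher on the log2 scale in that control than in the series 1 control. Their falls thus cannot be told apart from a control that stands apart. Adenylate cyclase 2 (Fcc02765) rose 1.47-fold and the nicotinic acetylcholine receptor beta subunit (Fcc01227) fell at least 1.16-fold, and the call of each was lost in 3 alternatives, with highest adjusted p-values of 0.129 and 0.26 over all refits. Fcc05781 rose 5.13-fold (2.36 ± 0.35), Fcc02261 rose 4.19-fold (2.07 ± 0.31), Fcc05623 fell 3.07-fold (-1.62 ± 0.25) and Fcc06064 fell by 1.42 on the log2 scale. In all, 25 genes changed, 15 up and 10 down, and 25 with the slide as a block. The split was 10 up and 12 down with the processed intensities and 9 up and 10 down with the deposited values, and the count was 15 without cobalt EC50 replicate 5 and 14 without control replicate 5.

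At EC10 of cobalt, hepatopancreas trypsin (Fcc05730) fell 2.27-fold (-1.18, adjusted p = 5.61e-06), while Fcc00270 rose 3.45-fold (1.79 ± 0.41, adjusted p = 0.0207) and Fcc02291 rose 4.31-fold (2.11 ± 0.34, adjusted p = 0.000167). The trypsin fell in all 6 comparisons against the series 2 control, so its fall is not particular to cobalt. At EC10 of cobalt 20 genes changed, 15 up and 5 down, and 13 with the slide as a block. The count was also 13 without cobalt EC10 replicate 2 and without control replicate 5. Between the doses limma called 0 genes (164 at an unadjusted p under 0.05, 0 with the slide block), and JTV1 (Fcc00446) stood at 0.34 ± 0.12, a NADH dehydrogenase (Fcc04753) at -0.60 ± 0.22 and Trypsin I (Fcc00536) at -0.54 ± 0.20, all with an adjusted p of 0.812.

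At EC50 of chromium, the starch-degrading amylase-3 (Fcc01171) rose 7.96-fold (2.99 ± 0.15, adjusted p = 1.37e-21) and cellulase (Fcc05266) 4.72-fold (2.24 ± 0.39, adjusted p = 2.15e-05), each in 4 of 4 samples. The other large rises were in glycine receptor alpha 1 (Fcc01574, 6.72-fold), 2 isopenicillin N synthetases of beta-lactam synthesis (Fcc00057, 6.13-fold, and Fcc01821, 4.77-fold), prepro actinohivin (Fcc01646, 5.83-fold), a DBH-like monooxygenase (Fcc00415, 4.88-fold), whey acidic protein core (Fcc01910, 2.19 ± 0.27 on the log2 scale) and PAPI I (Fcc00311, 4.23-fold). The extracellular matrix protein dumpy (Fcc01510) fell 11.3-fold (-3.50 ± 0.69, adjusted p = 0.000128) and a pacifastin-related protease inhibitor (Fcc01941) 8.48-fold (-3.08, adjusted p = 0.00221). Also lower were the thioredoxin-related gene Fcc05401 (6.44-fold), cyclopropane fatty acyl phospholipid synthase (Fcc00137, 5.58-fold), the peptidylprolyl isomerase ROC4 (Fcc02328, 5.53-fold), the kinase Cbk1p (Fcc02405, -1.61 ± 0.42) and 2 membrane peptidases, neutral endopeptidase (Fcc02046, -1.51 ± 0.50) and neprilysin 1 (Fcc02998, -1.36). Among genes with no name, Fcc02233 rose 18.2-fold (4.18 ± 0.21) and Fcc00354 rose by 4.23 ± 1.54, while Fcc01097 fell 38.3-fold (-5.26 ± 1.36) and Fcc02721 fell 25.5-fold (-4.67 ± 1.15). In all, 889 of 4401 genes changed, 504 up and 385 down, and 841 with the slide as a block. The split was 398 up and 462 down with the processed intensities and 413 up and 460 down with the deposited values. The call of Fcc00354 was lost in 4 alternatives, and those of Fcc05401, Fcc02046 and Fcc02998 with the number block.

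Of the 35 ribosome genes, 24 fell and 0 rose at EC50 of chromium (28 and 0 adjusted over the list alone), with a median of -0.451. Examples are ribosomal proteins L11 (Fcc04265, -0.65 ± 0.11), L35e (Fcc05736, -0.57 ± 0.09), S15a (Fcc00119, -0.61 ± 0.10) and S5e (Fcc04899, -0.65 ± 0.15). Of 18 phase II conjugation genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with the glutathione transferases Fcc04073 (2.48-fold, adjusted p = 2.58e-06), Fcc06274 (2.43-fold), Fcc02849 (1.95-fold) and the omega class member Fcc02471 (1.85-fold), enzymes that couple glutathione to foreign compounds. Of 9 carbohydrate hydrolases 3 rose (3 adjusted over the list alone), the third being beta-glucosidase 1 (Fcc03915, 1.55-fold). Cytochrome P450 4C1 (Fcc01417, 2.15-fold) and P450 4c3 (Fcc05132, 0.38 ± 0.13) rose among 13 P450 genes (2 and 0 adjusted over the list alone). Heat shock protein 70 (Fcc02719), a chaperone, rose 1.84-fold (0.88 ± 0.13, adjusted p = 1.11e-06) and TCP chaperonin (Fcc01180) fell by 0.44 on the log2 scale, the 2 of 10 heat shock genes that passed (1 up and 1 down adjusted over the list alone). The ABC transporter Fcc00582 of subfamily C, a family that exports conjugated compounds, rose 2.10-fold (1.07 ± 0.14) and Fcc03573 fell by 0.59 on the log2 scale among 8 members (2 up and 1 down adjusted over the list alone). Phospholipid hydroperoxide glutathione peroxidase (Fcc06123, -0.82 ± 0.26) and Fcc05401 fell among 12 antioxidant genes (0 up and 2 down adjusted over the list alone).

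Also at EC50 of chromium, the ubiquitin-conjugating enzyme-like gene Fcc06253 rose 2.19-fold, and proteasome beta subunit (Fcc05021, -0.43 ± 0.11), proteasome Z subunit (Fcc00064, -0.32 ± 0.11) and SUMO (Fcc00880, -0.30 ± 0.10) fell, of 18 proteasome and ubiquitin genes (1 up and 4 down adjusted over the list alone). Of 10 nervous system genes, nicotinic acetylcholine receptor type F (Fcc00279, 2.22-fold) and a muscarinic acetylcholine receptor (Fcc02109, 0.83 ± 0.14) rose and Fcc01227 fell at least 1.15-fold (3 up and 1 down adjusted over the list alone). NADH dehydrogenase subunits 4 (Fcc04995, 0.58 ± 0.19) and 5 (Fcc00793, 0.46 ± 0.13), both mitochondrial, rose of 14 respiration genes (2 and 0 adjusted over the list alone). Leucine aminopeptidase (Fcc01362, 0.96 ± 0.28) rose and hepatopancreas trypsin (Fcc05730, -1.03 ± 0.16) fell of 10 digestive proteases (1 up and 2 down adjusted over the list alone). This trypsin fell in all 6 comparisons against the series 2 control. Lipoprotein lipase (Fcc06038, 0.52 ± 0.14) rose and delta5 desaturase (Fcc04390, -0.53 ± 0.17) fell of 20 lipid genes (1 up and 1 down adjusted over the list alone). Endochitinase (Fcc02522, 0.63 ± 0.18) rose of 6 cuticle and chitin genes (1 and 0 adjusted over the list alone), the yolk protein vitellogenin I (Fcc05618, 0.57 ± 0.18) of 2 egg yolk genes (1 and 0), and Fcc03722 fell by 0.83 of 5 bacterial genes (0 and 1). Of 7 beta-lactam genes 2 rose (4 up and 1 down adjusted over the list alone), and 0 of 6 immunity (1 and 1), 0 of 7 muscle (0 and 0), 0 of 2 metal binding (0 and 1) and 0 of 1 DNA damage genes passed. The calls of Fcc02522 and Fcc05618 were lost with the processed intensities and the deposited values, those of Fcc03915 and Fcc00793 with the processed intensities, that of Fcc05132 in 3 alternatives, that of Fcc00064 in 3, and that of Fcc06123 with the number block.

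**Figure D1:**
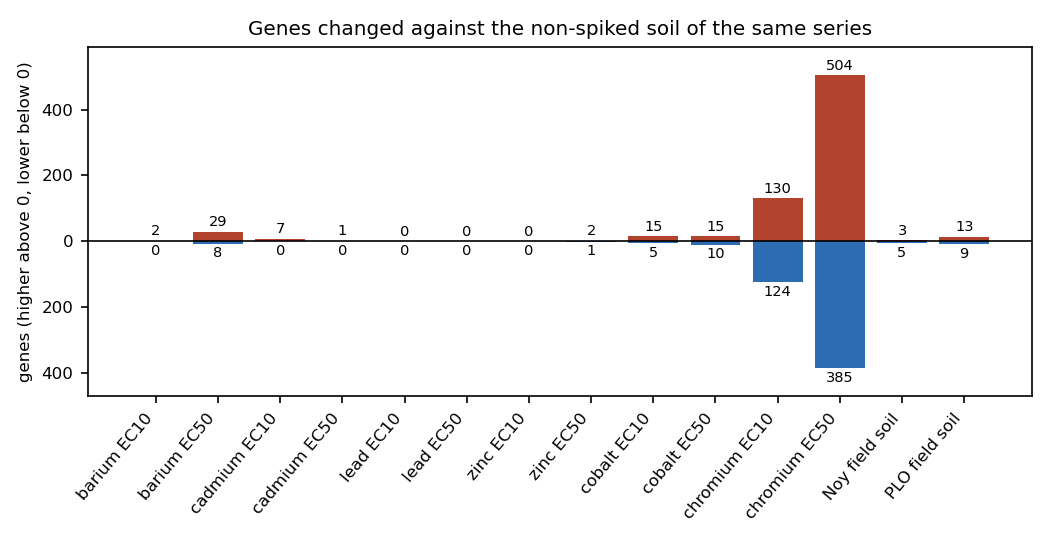
Number of genes that rose (bars above 0) and fell (bars below 0) past an adjusted p of 0.05 in each metal or field soil group against the clean soil control of its series. Chromium EC50 had 504 genes up and 385 down, chromium EC10 130 and 124, and the lead groups 0.

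At EC10 of chromium, amylase-3 (Fcc01171) rose 2.30-fold (1.20 ± 0.15, adjusted p = 1.01e-07), the glutathione transferases Fcc04073 (1.89-fold, adjusted p = 0.00257) and Fcc02849 (0.55 ± 0.17) and the ABC transporter Fcc00582 (0.49 ± 0.14) rose, and antimicrobial peptide Alo2 (Fcc05968) fell 3.53-fold (-1.82 ± 0.34, adjusted p = 0.000255). Glutathione peroxidase Fcc06123 fell by 0.86, proteasome alpha subunit Fcc04573 fell by 0.50, and hepatopancreas trypsin (Fcc05730) fell 2.25-fold, as it did in all 6 comparisons against the series 2 control. The receptor subunit Fcc01227 fell at least 1.21-fold. Of 35 ribosome genes 4 fell (7 adjusted over the list alone), which were S5e (Fcc04899, -0.50), S15a (Fcc00119, -0.39), S11 (Fcc01914, -0.35) and S27 (Fcc00431, -0.33). In all, 254 genes changed, 130 up and 124 down, and 295 with the slide as a block. The split was 110 up and 152 down with the processed intensities and 111 up and 145 down with the deposited values. The calls of Fcc00582 and Fcc01914 were lost with the slide block, and that of Fcc02849 in 3 alternatives. The count was 164 without chromium EC10 replicate 2, 153 without replicate 3, 148 without replicate 4 and 165 without control replicate 3.

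From EC10 to EC50 of chromium, amylase-3 (Fcc01171) rose a further 3.46-fold (1.79 ± 0.15, adjusted p = 2.11e-12), glutathione transferase Fcc06274 rose 2.14-fold (1.1 ± 0.25, adjusted p = 0.00543), heat shock protein 70 (Fcc02719) rose by 0.55 ± 0.13, the ABC transporter Fcc00582 by 0.58 ± 0.14, cytochrome P450 CYP6N4v1 (Fcc01651) by 0.65 ± 0.19 and muscarinic receptor Fcc02109 by 0.52 ± 0.14. The Hsc70/Hsp90-organizing protein (Fcc04047) fell by 0.55, TCP chaperonin (Fcc01180) by 0.45, L11 (Fcc04265) by 0.44 and L35e (Fcc05736) by 0.34 on the log2 scale. Among genes with no usable name, Fcc02233 rose 4.35-fold and Fcc02517 3.96-fold, and Fcc00222 (-2.55) and Fcc02914 (-1.89) fell. In all, 135 genes changed, 108 up and 27 down, and 138 with the slide as a block. With the processed intensities the count was 78, 43 up and 35 down, and the calls of Fcc02719, Fcc00582, Fcc01651, Fcc02109, Fcc02517, Fcc00222 and Fcc02914 were lost, and that of Fcc05736 was lost with no dye term. With the number block the split was 92 up and 54 down. The count was 209 without chromium EC50 replicate 2, 58 without replicate 3, 82 without replicate 4, 72 without replicate 5, 87 without EC10 replicate 2 and 60 without EC10 replicate 3.

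**Figure D2:**
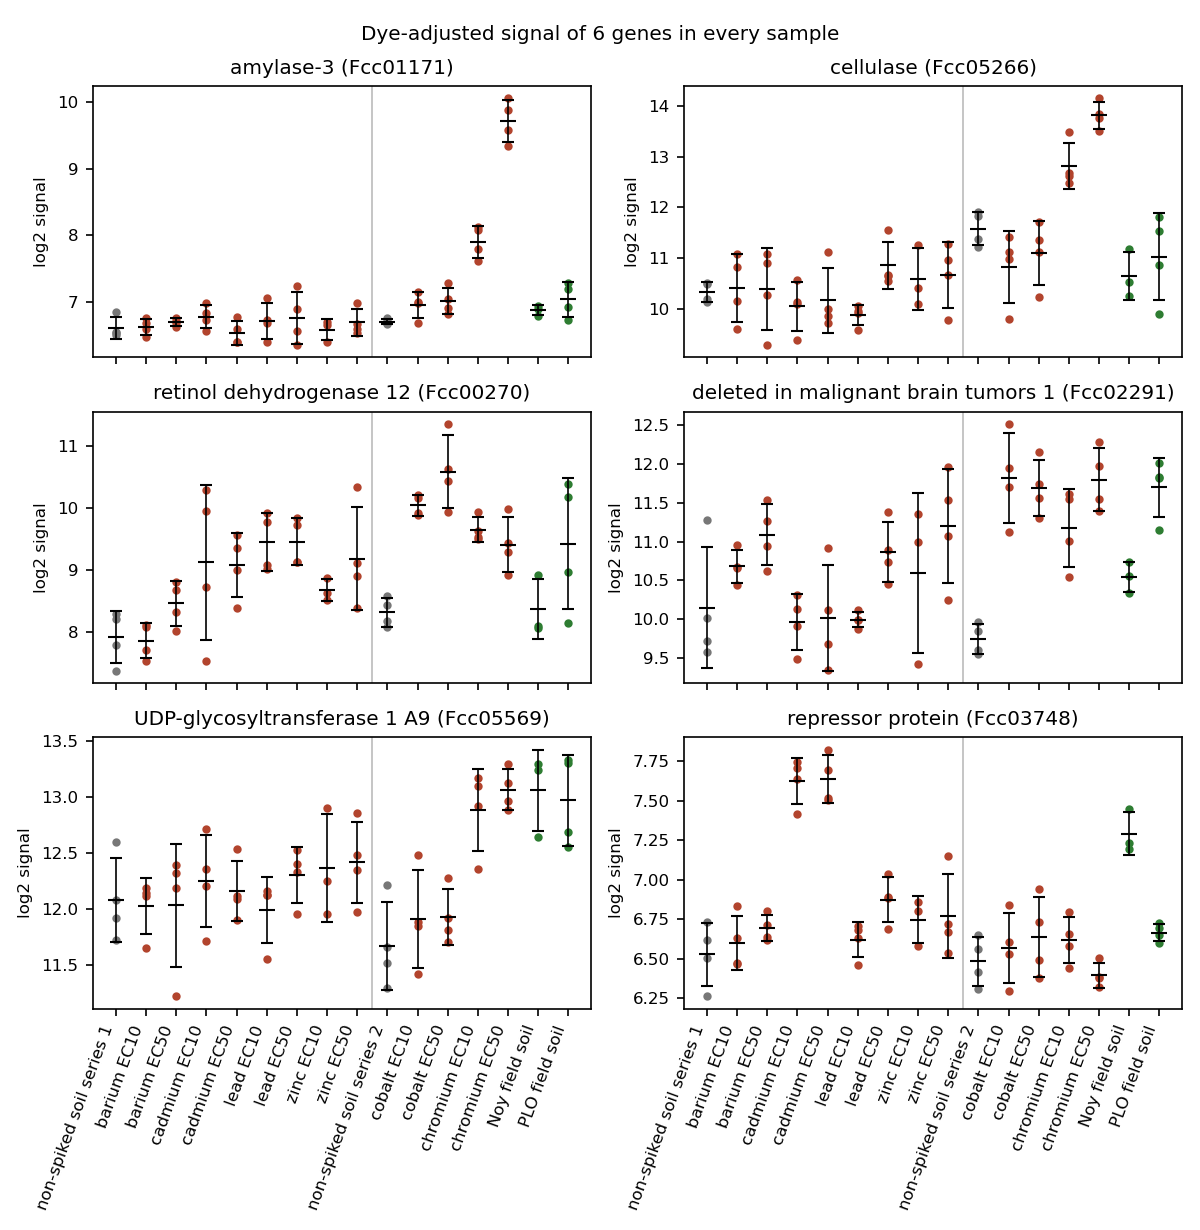
Dye-adjusted log2 signal of 6 named genes in each sample (points), by group, with the group mean and SD (bars). Amylase-3 was 7.96-fold higher in chromium EC50 soil than in the series 2 control, and repressor protein 2.17-fold higher in cadmium EC10 soil than in the series 1 control.

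The field soil Noy, with 3 samples, raised UDP glycosyltransferase A9 (Fcc05569), a conjugating enzyme, 2.62-fold (1.39, adjusted p = 0.00497), and the cadmium-responding repressor protein (Fcc03748) 1.77-fold (0.83, adjusted p = 6.49e-05). Antimicrobial peptide Alo2 (Fcc05968) fell 5.06-fold (-2.34 ± 0.37, adjusted p = 0.000118), putative protein disulfide isomerase (Fcc04354) 2.81-fold (-1.49 ± 0.20, adjusted p = 5.83e-06) and hepatopancreas trypsin (Fcc05730) 2.01-fold (-1.01 ± 0.18, adjusted p = 0.000894). Fcc04354 and Fcc05730, and Fcc05623 below, fell in all 6 comparisons against the series 2 control. Of the genes with no name, Fcc00834 rose by 0.71 ± 0.14, and Fcc05623 (-1.34 ± 0.27) and Fcc04792 (-1.1) fell. These were all 8 genes, 3 up and 5 down, and 10 passed with the slide as a block. The split was 6 up and 6 down with no background correction and 3 up and 7 down with the processed intensities, where the call of trypsin was lost (adjusted p = 0.0591). The count was 5 without Noy replicate 2 and 5 without replicate 3.

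The field soil PLO, with 4 samples, raised deleted in malignant brain tumors 1 (Fcc02291) 3.87-fold (1.95 ± 0.34, adjusted p = 0.000374), UDP glycosyltransferase A9 (Fcc05569) 2.44-fold (1.29 ± 0.25, adjusted p = 0.00241) and putative cytoplasmic protein (Fcc00376) 2.33-fold (1.22 ± 0.25). Putative protein disulfide isomerase (Fcc04354) fell 2.68-fold (-1.42 ± 0.18, adjusted p = 8.04e-07), putative core protein (Fcc00928) by 1.25 on the log2 scale and hepatopancreas trypsin (Fcc05730) 2.13-fold (adjusted p = 2e-05). Of these, Fcc04354 and Fcc05730 fell in all 6 comparisons against the series 2 control, as did Fcc05623 below. The gene Fcc03289 rose by 3.46 ± 0.37 and Fcc06085 rose 4.9-fold (2.29 ± 0.23), while Fcc05623 fell 3.19-fold and Fcc02190 by 1.40. In all, 22 genes changed, 13 up and 9 down, and 22 with the slide as a block. The count was 14 without PLO replicate 3.

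Between the field soils 6 genes differed, 3 higher in Noy and 3 higher in PLO, and 6 with the slide as a block. Higher in Noy were repressor protein (Fcc03748, 0.66 ± 0.12, adjusted p = 0.00229), Fcc00472 (at least 2.71-fold, adjusted p = 6.81e-06) and Fcc00834 (0.83 ± 0.13). Higher in PLO were Fcc03289 (Noy minus PLO -2.57 ± 0.39), Fcc02441 (-2.07 ± 0.46) and Fcc06085 (-1.58 ± 0.24), the last chosen after its values were seen. The split was 2 and 4 with the processed intensities, where the call of Fcc03748 was lost, and the count was 10 without PLO replicate 1.

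The 2 clean soil controls differed in 1 gene, hepatopancreas trypsin (Fcc05730), which was 2.01-fold higher in series 2 than in series 1 (adjusted p = 0.000562) in 4 of 4 samples, and in 1 gene with the slide as a block. It fell in all 6 comparisons against the series 2 control. With the processed intensities 0 genes differed (adjusted p = 0.111), and with the deposited values 2 did. The count was 5 without series 2 control replicate 1, 4 without replicate 5, 4 without series 1 control replicate 1 and 2 without replicate 3.

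Among barium, cadmium, lead and zinc, with each metal's mean of EC10 and EC50 set against the control, limma's F test found 88 genes, and 77 with the slide as a block. Repressor protein (Fcc03748) differed most (F = 62.1, adjusted p = 7.09e-13), with 0.12 for barium, 1.1 for cadmium, 0.22 for lead and 0.23 for zinc. Glutamate dehydrogenase (Fcc04585, adjusted p = 3.45e-05) stood at 0.68 for barium, 0.01 for cadmium, 0.33 for lead and 0.12 for zinc. The antimicrobial peptide genes spodomicin (Fcc00326, adjusted p = 0.00168) and Alo2 (Fcc05968, adjusted p = 0.00475) stood at 0.16, 0.75, -0.33 and -0.42 and at 0.74, 0.40, -0.36 and -0.36 in the same order of metals. The ABC transporter Fcc00181 (adjusted p = 0.00152) stood at 0.39, 0.07, -0.39 and -0.18. Cystatin A2 (Fcc02429), fibulin 2 (Fcc05158), Fcc03114, a second spodomicin (Fcc03130) and fed tick salivary protein 5 (Fcc05793) complete the 10 named genes of highest F. The count was 180 without barium EC50 replicate 1, 44 without barium EC50 replicate 2, 53 without cadmium EC10 replicate 2 and 191 without lead EC10 replicate 2.

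Cobalt and chromium, each over both doses, differed in 730 genes, 294 higher with cobalt and 436 higher with chromium, and in 754 with the slide as a block. Carbohydrate hydrolases were higher with chromium in 5 of 9 genes and with cobalt in 0 (5 and 0 adjusted over the list alone). Cobalt minus chromium was -2.36 ± 0.29 for cellulase (Fcc05266, adjusted p = 1.2e-08), -1.81 ± 0.11 for amylase-3 (Fcc01171, adjusted p = 3.38e-18), -0.85 for maltase-glucoamylase (Fcc00529) and -0.76 for preamylase (Fcc02249). Of 35 ribosome genes 23 were higher with cobalt and 0 with chromium (28 and 0 adjusted over the list alone), with a median of 0.298, as S29e (Fcc02068, 0.58 ± 0.17) and S23e (Fcc00291, 0.43 ± 0.09). Of 12 antioxidant genes, thioredoxin-related Fcc05401 (2.42 ± 0.58), thioredoxin H (Fcc00677) and glutathione peroxidase Fcc06123 (0.87 ± 0.19) were higher with cobalt and superoxide dismutase 1 (Fcc00755, -0.32 ± 0.11) with chromium (3 and 1 adjusted over the list alone). Of 18 phase II genes 3 were higher with chromium (3 adjusted over the list alone), with glutathione transferase Fcc04073 at -0.94 ± 0.15 (adjusted p = 4.09e-06). Nicotinic receptor type F (Fcc00279, -1.19 ± 0.17) and endochitinase (Fcc02522, -0.92 ± 0.13) were higher with chromium, and antimicrobial peptide Alo2 (Fcc05968, 0.85) with cobalt. Of 18 proteasome and ubiquitin genes 7 were higher with cobalt and 1 with chromium (7 and 1 adjusted over the list alone). The call of Fcc00755 was lost with the slide as a block.

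Across all lists and comparisons, camera with the preset correlation called 14 of 238 shifts, and 0 with an estimated correlation, 4 with fry and 2 with fry's mixed test. The fry test sets a list against no change and not against other genes. It called the ribosome in chromium EC50 (adjusted p = 4.5e-06) and EC10 (0.0242) and carbohydrate hydrolases in chromium EC50 (1.59e-06). Its other call, of phase II genes (0.041), lay outside lead EC50, where its adjusted p was 0.544. With the slide as a block camera called 18, 13 of them shared with the 14. The 35 ribosome genes, whose products build proteins, were lower than other genes in 7 comparisons. Their median was -0.451 in chromium EC50 (adjusted p = 1.65e-12, and adjusted p = 0.594 with an estimated correlation), -0.289 in chromium EC10 (7.1e-09, and 0.888 with an estimated correlation), -0.234 in barium EC50 (1.6e-08, and 0.888), -0.102 in zinc EC10 (0.000531, and 0.888), -0.0892 in zinc EC50 (0.00435, and 0.939), -0.133 in Noy (0.000101, and 0.888) and -0.116 in PLO (0.00238, and 0.935). Outside chromium 0 ribosome genes passed on their own in these comparisons, and simulated falls of the list by 0.1 were recovered in 0 of 10 draws and falls by 0.2 in at most 3 of 10, so the calls with small medians lie below what the simulation recovered. Proteasome and ubiquitin genes were lower in barium EC50 (median -0.146, adjusted p = 0.0257) and chromium EC10 (-0.203, adjusted p = 0.0209), each with an adjusted p of 0.888 with an estimated correlation. Carbohydrate hydrolases were higher in chromium EC50 (0.533, adjusted p = 0.0248, and adjusted p = 0.888 with an estimated correlation), a call lost with the processed intensities (adjusted p = 0.0739). Beta-lactam synthesis genes were lower in lead EC10 (-0.489, adjusted p = 0.0101, and 0.888 with an estimated correlation), and phase II genes higher in lead EC50 (0.118, adjusted p = 0.0167, and 0.888). Both calls were lost in camera with the number block (adjusted p = 0.0526 and 0.0676). In cobalt EC10, heat shock genes were higher (0.137, adjusted p = 0.00954, and adjusted p = 0.594 with an estimated correlation), as were mitochondrial respiration genes (0.158, adjusted p = 0.0409, and 0.888). This last call was lost with the processed intensities (adjusted p = 0.2), the deposited values (0.139) and the slide block (0.216). In all 14 shifts the median kept its sign in the 4 other scalings and fits.

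The other lists were called in 0 of 14 comparisons with camera. Their lowest adjusted p was 0.0508 for antioxidant enzymes (PLO, median -0.217, and adjusted p = 0.0389 with the number block, which passes, as it does in barium EC50 at 0.0471 and chromium EC10 at 0.041), 0.0537 for digestive proteases (cobalt EC50, -0.204), 0.0558 for lipid metabolism (barium EC50, -0.186), 0.0853 for ABC transporters (lead EC10, -0.144), 0.0854 for cytochrome P450 (zinc EC10, -0.0769, and adjusted p = 0.0498 with the number block), 0.138 for immunity (zinc EC10, -0.222), 0.233 for bacterial genes (cobalt EC50, -0.202), 0.365 for cuticle and chitin (lead EC50, 0.128), 0.486 for muscle (chromium EC50, 0.117) and 0.641 for the nervous system (Noy, 0.0166). The lists that were too small held 2 metal binding genes, secreted ferritin (Fcc04961), an iron store, between -0.14 and 0.07 over the 14 comparisons (lowest adjusted p = 0.619), and a copper transporter (Fcc04079) between -0.22 and 0.15 (lowest adjusted p = 0.0945). They also held DNA mismatch repair protein (Fcc02956, lowest adjusted p = 0.458), vitellogenin I (Fcc05618), which passed in 1 of 14 comparisons, and vitelline membrane outer layer protein 1 (Fcc05544, lowest adjusted p = 0.424).

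**Figure D3:**
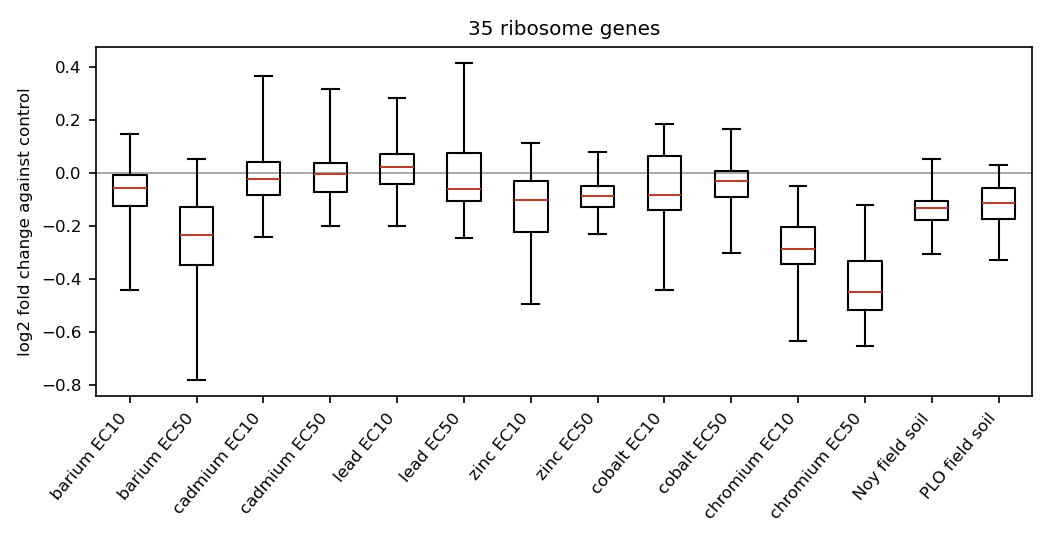
Log2 fold changes of the 35 ribosome genes in each comparison against the control, as boxes from the lower to the upper quartile with the median as a line and whiskers to the lowest and highest gene. The median was -0.451 in chromium EC50, -0.289 in chromium EC10 and -0.234 in barium EC50.

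Responses to the metals at EC50 were compared across 4401 genes, which are not independent replicates. Barium and chromium, from different series with no shared control, had r = 0.519 and rho = 0.357, and 24 genes rose in both (independent lists would give 3.32) and 5 fell in both (0.7), with 2 in opposite directions. The values by independent lists treat genes as independent of each other, and the barium list had 19 to 80 genes with 1 sample left out. Cobalt and chromium shared a control and had r = 0.409, a simulated value of 0.486 with no effect and 0.213 with the control split, and a covariance of 0.0967 against a simulated 0.0374, with 12 genes up in both (1.72 by independent lists) and 7 down in both (0.875). The values by independent lists leave out the shared control, and 3 of the 7 fell in all 6 comparisons against it (Fcc05730, Fcc04354 and Fcc05623). Barium and zinc had r = 0.635, simulated 0.506, and 0.0929 with the control split (covariance 0.0588 against a simulated 0.0401). Over the 15 pairs of metals the median r was 0.409, between 0.225 and 0.635. In the 7 pairs that shared a control the median was 0.409, against 0.505 simulated and -0.0589 with the control split, and in the others it was 0.378.

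PLO and barium EC50, with no shared control, had r = 0.45 and rho = 0.488 (simulated 0.0327, covariance 0.059 against 0.0026), with 1 gene up in both (0.0857 by independent lists) and 1 down (0.0164). The simulation leaves out variation that genes share between samples, so it cannot tell how far this r exceeds one with no effect. The correlation across genes of PLO and cobalt EC50 was r = 0.763 and rho = 0.601, against a simulated 0.495 for their shared control and 0.379 with the control split (between 0.278 and 0.479), and the covariance was 0.109 against a simulated 0.0387. They shared 4 genes up (0.0443 by independent lists) and 7 down (0.0204). The same 3 genes are among these 7. PLO and chromium EC50 had r = 0.443 (simulated 0.493, 0.223 with the control split, covariance 0.0951 against 0.0383), with 8 genes up in both (1.49) and 5 down (0.787), the same 3 among them. Noy and cobalt had r = 0.585 (simulated 0.461, 0.2 with the control split, covariance 0.0726 against 0.0388), with 4 genes down in both (0.0114). The same 3 genes, which fell in all comparisons against the shared control, are among these 4. Noy and chromium had r = 0.0776 (simulated 0.456, -0.1 with the control split, covariance 0.0145 against 0.0382), and Noy and PLO r = 0.522 (simulated 0.484, 0.132 with the control split, covariance 0.0588 against 0.0412). Over the 12 pairs of a field soil and a metal the median r was 0.261, between -0.0607 and 0.763. In the 4 pairs that shared a control the median was 0.514, against 0.477 simulated and 0.212 with the control split, and in the others it was 0.213.

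**Figure D4:**
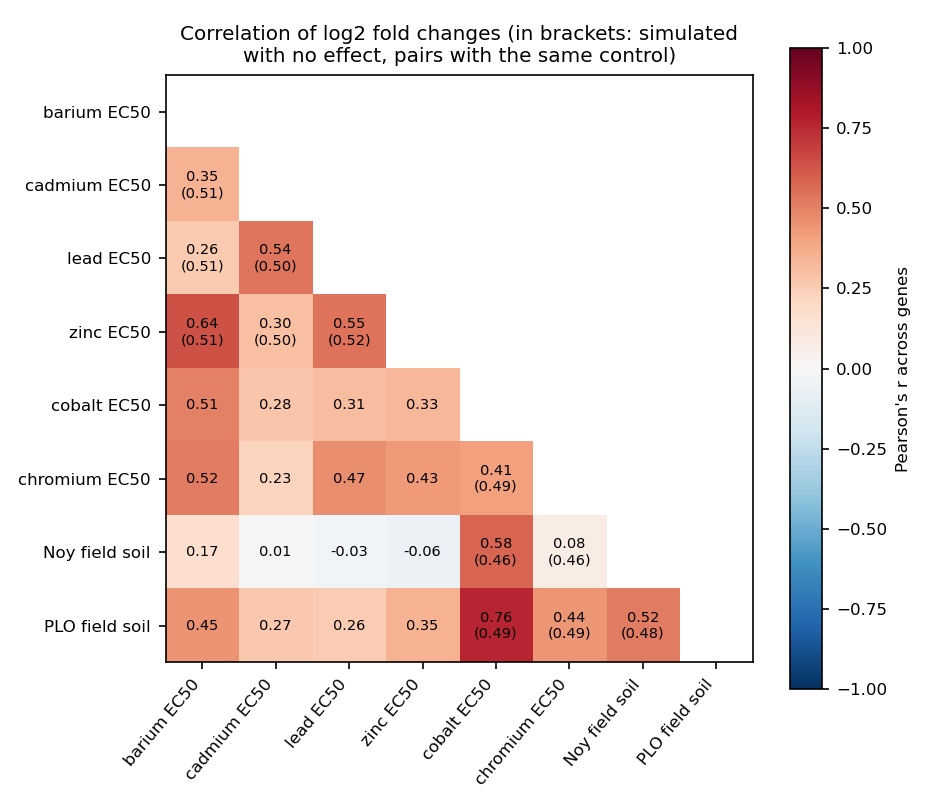
Pearson's r across genes between the log2 fold changes of the metals at EC50 and the field soils, as colour and number, with the value simulated with no effect in brackets for pairs that share a control. PLO and cobalt had r = 0.763, against a simulated 0.495.

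The classifier used 190 genes at a shrinkage of 2 and a correlation threshold of 0.7. In the 43 training samples it placed 35 in their own class when their array was left out, which was 81.4%. The settings were chosen for the highest such count, so this share can overstate the accuracy. Right were 6 of 6 barium, chromium and cobalt samples, 5 of 6 cadmium, 3 of 6 lead, 3 of 6 zinc and 6 of 7 clean soil samples. Of the 12 validation samples 9 (75%) were placed in their own class, with a permutation p of 1e-05, the smallest that the permutations can give, and a permutation p of 6e-04 when labels were permuted within the series. A cadmium EC50 sample was placed in clean soil (distance 100.9 against 104.1 to its own class), and a lead EC10 sample (78.02 against 78.72) and a lead EC50 sample (53.39 against 55) in zinc. The number right was 8 without the removal of correlated genes, 8 when lead EC10 replicate 2 or zinc EC50 replicate 3 was left out of training, and 9 in the 3 other alternatives. The only zinc validation sample was right by a small margin (129.3 against 130.6 to the next class). It went to chromium without the removal of correlated genes and to lead with the processed intensities. With the processed intensities the lead EC10 sample was right instead (185.7 against 186.7).

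Chromium was marked by the largest number of genes of the classifier (85), with a gene free to mark several classes, followed by barium (36), cadmium (33), cobalt (26), clean soil (24), zinc (13) and lead (7). Named genes with the largest shrunken scores were repressor protein (Fcc03748, 3.47), spodomicin (Fcc00326, 1.66) and lectin 2a (Fcc02832, 1.27) for cadmium, Alo2 (Fcc05968, 1.33), fed tick salivary protein 5 (Fcc05793, -1.17) and the sterol-binding Niemann-Pick C2 (Fcc05876, 1.04) for barium, and dumpy (Fcc01510, -3.64), Alo2 (-2.71) and glycine receptor alpha 1 (Fcc01574, 1.53) for chromium. For cobalt they were group 2 allergen (Fcc04297, -1.55), Fcc02291 (1.42) and vitelline membrane outer layer protein 1 (Fcc05544, 0.55), for zinc nitrilase 2 (Fcc02640, -0.57), a GDSL lipase (Fcc01037, -0.40) and electron carrier (Fcc05985, 0.11), for lead Fcc04605 (0.70), and for clean soil Fcc00270 (-1.81), hepatopancreas trypsin (Fcc05730, 1.45) and Fcc02291 (-0.94). All 4 PLO samples were placed with cobalt, a metal of the same series, though every sample had to be given 1 of the 7 classes. Distances to cobalt and to the next class were 211.7 and 215.5 for replicate 1 and 125.5 and 134.6 for replicate 2. They were 122.1 and 130.5 for replicate 3 and 93.45 and 96.15 for replicate 4. The cobalt validation samples lay at 89.15 (EC10) and 120.6 (EC50) from their class. Of the 3 Noy samples, replicate 2 was placed with cobalt and replicates 3 and 5 with clean soil. PLO replicate 1 went to barium without the removal of correlated genes, PLO replicate 4 to lead with the processed intensities, and Noy replicate 3 to cobalt in 3 of the 4 alternatives.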

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

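The tests of the common axis, of the scaling of the ribosome list, of the series 2 control and of other splits of the samples were chosen after the results were seen, as were the tests of the step from EC10 to EC50, while the comparison of the ribosome list with matched lists was chosen before.

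Cobalt and chromium, each set against the same clean soil, differed in 730 genes under the same contrast. Among barium, cadmium, lead and zinc 88 genes passed, between 44 and 191 with 1 sample left out, and another grouping of these samples called 528. The step from EC10 to EC50 differed between cobalt and chromium in 32 genes by an interaction test in limma, with a smaller step for cobalt in 29 and a larger one in 3. Cobalt minus chromium was -1.73 ± 0.21 for amylase-3 (Fcc01171, adjusted p = 4.92e-07), -1.49 ± 0.21 for polyketide synthase (Fcc00397, adjusted p = 1.13e-05), -1.42 ± 0.36 for the antimicrobial peptide theromacin (Fcc05207, adjusted p = 0.0385), -1.40 ± 0.35 for glutathione transferase Fcc06274 (adjusted p = 0.0347) and -1.27 ± 0.31 for a putative cyclase (Fcc04425, adjusted p = 0.0315). In the 6 pairs of series 1 metals the step differed in 0 genes, with between 34 and 273 at an unadjusted p under 0.05.

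In 9 of 160 groups of 4 samples of a named gene, 1 sample lay far from the other 3 by Dixon's test, and chance alone marks about 1 in 20 groups. In chromium EC10, replicate 4 had a log2 level of 14.66 for ribosomal protein S15a (Fcc00119), against a mean of 14.34 in the others. In chromium EC50, replicate 3 had 10.68 for a muscarinic receptor (Fcc02109, others 10.3) and 12.82 for vitellogenin I (Fcc05618, others 12.43), and replicate 2 had 15.36 for ribosomal protein L11 (Fcc04265, others 14.95). In the series 2 control, replicate 1 had 6.93 for monooxygenase Fcc00415 (others 6.122), replicate 2 had 6.307 for receptor subunit Fcc01227 (others 6.533), and replicate 3 had 10.52 for leucine aminopeptidase (Fcc01362, others 10.21), 7.585 for adenylate cyclase 2 (Fcc02765, others 8.003) and 12.07 for proteasome beta subunit (Fcc05021, others 11.81).

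Samples of the same group differed along a common axis that held 25% of the variance within groups. Its permutation p for slide and dye was 0.441, with 8% accounted for. The dye term had been taken out of the values before the axis was drawn, so this p cannot speak for or against dye. The 2 samples of an array did not share a place on the axis (r = 0.0504, permutation p = 0.784, and rho = 0.0669, permutation p = 0.717, over 31 arrays, with r = -0.0307 without the 2 farthest). Slide and hybridisation on 1 array are thus argued against as sources of the axis. Brightness cannot be told apart from it, since the axis ran with the median net signal in the Cy3 samples (r = -0.653, permutation p = 0.00011, adjusted 0.00033; rho = -0.6, permutation p = 0.00042, adjusted 0.00126; r = -0.555 without the 2 farthest, -0.611 within slides) and less in the Cy5 samples (r = -0.378, permutation p = 0.0366, adjusted 0.0549; rho = -0.338, permutation p = 0.0633, adjusted 0.0949; r = -0.303 without the 2 farthest, -0.411 within slides), with 31 samples each and 3 relations tested. The moult stage of the pools cannot be told apart either, since the 6 cuticle and chitin genes loaded on the axis with a mean size of 0.243 (percentile 95.2 of 10000 lists matched on level) and a signed mean of 0.00194, while beta-lactam synthesis genes (0.314, percentile 99.8) and digestive proteases (0.21, percentile 96.8) stood higher among their matched lists.

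The fall of the ribosome list in chromium EC50 soil was set against a bias of bright genes and against the scaling. Its median of -0.451 lay below the 2.5th percentile of -0.203 of 10000 lists matched on level. Its highest median over the scalings and the slide-block fit was -0.443. A bias shared by genes of like level thus does not account for the fall, nor does the choice among these scalings. The matching used broad bins of level, so it cannot exclude a bias of the brightest genes alone. Every scaling brings the samples to a common level, so an error that all of them share is not excluded either. The design names the chromium dose as a biological difference, and the fall may be tied to it, but 0 of the list calls held with an estimated correlation, and growth or feeding of the animals was not measured here.

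Fallen in at least 3 of the 6 comparisons against the series 2 control were 9 genes, and 3 of them fell in all 6: hepatopancreas trypsin (Fcc05730), putative protein disulfide isomerase (Fcc04354) and Fcc05623. Only trypsin differed between the 2 controls (adjusted p = 0.000562), and Fcc05623, with a control difference of 0.42 (adjusted p = 0.999), also fell in 2 series 1 comparisons, barium EC50 (-1.35) and zinc EC50 (-1.16). The genes were picked for being lower than this control, so they were picked again against 2 of its 4 samples and the other 2 samples were compared with the series 1 control. The difference was a median of 0.536 of the fall from those 2 samples, between 0.21 and 0.673 over the 6 ways to halve the control, so a control that stands apart cannot be told apart from a response of these genes to all of the soils.

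For each count, other splits of the same samples into groups of the same sizes were counted, the real one included. Each share was taken alone: adjustment over the 24 counts gave a lowest share of 0.08, but 35 splits allow no share below 1 of 35 and the 7 counts of 0 are fixed at 35 of 35, so the adjusted shares decide little. No other split called as many genes for cadmium EC10 (7 genes, 1 of 35 splits as large, highest other 2), cobalt EC50 (25, 1 of 35, highest other 2) and chromium EC10 (254, 1 of 35, highest other 2). The same held for chromium EC50 (889, 1 of 35, highest other 418), the chromium step (135, 1 of 35, highest other 13) and Noy (8, 1 of 35, highest other 5). It also held for cobalt against chromium (730, 1 of 100 drawn, highest other 594). Taken alone these shares lay under 0.05, but 24 counts were tested and the lowest adjusted share was 0.08, so they do not exclude chance. The cadmium EC10 count fell to 2 without cadmium EC10 replicate 2 or 3, and the Noy count to 5 without Noy replicate 2 or 3. The share was also under 0.05 for barium EC10 (2, 1 of 35, highest other 1), though by 1 gene only. Among the series 1 metals it was too (88, 3 of 100 drawn, highest other 528), though another grouping called far more genes. The share lay above 0.05, and chance is not excluded either, for barium EC50 (37, 2 of 35, highest other 794) and cadmium EC50 (1, 5 of 35, highest other 13). This was also so for zinc EC50 (3, 3 of 35, highest other 6), cobalt EC10 (20, 2 of 35, highest other 22) and the barium step (9, 3 of 35, highest other 26). Noy against PLO (6, 2 of 35, highest other 15) and the controls (1, 4 of 35, highest other 3) were alike in this. For cadmium EC50 the count does not test its 1 gene, repressor protein (Fcc03748, adjusted p = 3.88e-09), which kept its call in every refit. In PLO (22, 2 of 35, highest other 48) the share also lay above 0.05. There 3 samples deviated together with the controls of the same number, but this was found in these same data and no label names a pairing. If the numbers do pair them, 8 splits part all 3 pairs, too few for a share under 0.05. The others of these called 0 genes, and the split with 48 kept all 3 pairs together. Since the pairs were found by their correlation, the split with 48 cannot be set aside on this ground. Counts of 0 were matched by 35 of 35 splits, with a highest other count of 3 for lead EC10, 6 for lead EC50, 27 for zinc EC10, 12 for the cadmium step, 30 for the lead step, 165 for the zinc step and 181 for the cobalt step.

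Several of these splits called many times the real count, which points to a structure of the samples other than their groups. The split of the barium EC50 and control samples that called 794 genes ranked 3 of 35 in how far it parted the samples along the common axis, and the cobalt split with 181 ranked 2. The zinc step split ranked 33, the lead step split 22 and the zinc EC10 split 19. None of these 5 splits followed the dye or a slide in all of its samples.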

How the results depend on the processing

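The alternatives and left-out samples were chosen before the data were examined, except for the gene lists, where the slide block, the number block, no background correction and the deposited values were added after, and the cause was not tested for any result that changed. Of 173 results of named genes past the threshold, 130 kept their direction and call in all alternatives, 102 also in every fit with 1 sample left out, and 0 reversed. Signal over background limited the dim genes, since 4401 of 5069 genes passed the filter.

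Counts moved by over 1.5 times in these cases. With the processed intensities cadmium EC10 had 3 genes, lead EC50 1, the barium step 5, the chromium step 78 and the controls 0. With the slide as a block lead EC50 had 1, cobalt EC10 13 and the barium step 3. With the deposited values lead EC50 had 1, zinc EC50 1 and the controls 2. Without the filter zinc EC10 had 1 and zinc EC50 1, and zinc EC50 also had 1 without background correction and 1 with no dye term. The list shifts fell to 0 with an estimated correlation. The median correlation between metals moved from 0.409 to 0.225 with the control split in the 7 of 15 pairs that shared one. In those 7 pairs alone it moved from 0.409 to -0.0589. Over called genes it was 0.622, and that of field soils with metals moved from 0.261 to 0.575. Called genes were picked for large changes and have no simulated value beside them. Validation samples placed right were 8 or 9 in all settings and left-out samples. The brightest probe per gene could not be run as an alternative, since each gene has 1 probe.

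Leaving out 1 sample at a time gave 1 to 2 genes for barium EC10, 19 to 80 for barium EC50, 2 to 14 for cadmium EC10, 1 to 4 for cadmium EC50, 0 to 18 for lead EC50, 0 to 2 for zinc EC10, 0 to 2 for zinc EC50, 13 to 17 for cobalt EC10, 14 to 26 for cobalt EC50, 148 to 242 for chromium EC10, 688 to 883 for chromium EC50, 1 to 9 for the barium step, 0 to 4 for the cadmium step, 0 to 2 for the zinc step and 58 to 209 for the chromium step. It gave 5 to 11 for Noy, 14 to 31 for PLO, 5 to 10 for Noy against PLO, 1 to 5 for the controls, 621 to 730 for cobalt against chromium and 44 to 191 among the series 1 metals, and 0 in every fit for lead EC10, the lead step and the cobalt step.

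With the replicate number as a block zinc EC50 had 1 gene, and no other count of genes moved by over 1.5 times (37 for barium EC50, 800 for chromium EC50). Under this block 18 list shifts were called against 14, with 12 shared; the beta-lactam call in lead EC10 (adjusted p = 0.0526) and the phase II call in lead EC50 (adjusted p = 0.0676) were lost. Gained were antioxidant enzymes in PLO (0.0389), barium EC50 (0.0471) and chromium EC10 (0.041), cytochrome P450 in zinc EC10 (0.0498), beta-lactam synthesis in cadmium EC50 (higher, 0.0169) and the ribosome in cobalt EC10 (0.0481). No label says that a number marks a shared batch, in PLO or elsewhere, and 12 of 62 samples correlated best with samples of their own number. Of the named genes 19 lost the call under this block, against 26 with the processed intensities.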

Other observations

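The overlap of barium and chromium is that of the comparison of responses in the report, and its genes and the other tests in this part were chosen after the results were seen.

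Barium and chromium at EC50, from separate series with separate controls, raised 24 genes in common and lowered 5, where independent lists would share 3.32 and 0.7. Those values treat genes as independent of each other. Another split of the barium EC50 and control samples called 794 genes against the real 37. Its overlap with the chromium genes was not counted, so no overlap with no effect stands beside the real one. The overlap alone thus does not show a common response to the 2 metals. Phosphoserine aminotransferase 1 (Fcc05461) rose by 0.93 ± 0.17 with barium and by 1.89 ± 0.17 with chromium (adjusted p = 1.97e-12), glutamate dehydrogenase (Fcc04585) by 0.88 ± 0.14 and 1.18 ± 0.14 (adjusted p = 2.96e-09), and cystatin A2 (Fcc02429) by 0.41 ± 0.10 and 0.60 ± 0.10 (adjusted p = 1.53e-05). The other 21 shared genes that rose have no usable name, among them Fcc03965 (1.78 ± 0.26 and 2.90 ± 0.26), Fcc00264 (1.87 and 3.34) and Fcc03576 (1.54 ± 0.23 and 2.78 ± 0.23). The gene Fcc05623 fell with both (-1.35 ± 0.25 and -1.41 ± 0.25).

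Within series 2, 20 genes rose in at least 3 of the 6 comparisons against the control. The 6 comparisons share the 4 control samples and no count with no effect was made, so their agreement does not show a response to all of these soils. Deleted in malignant brain tumors 1 (Fcc02291) rose in 5 of them, 4.08-fold in chromium EC50 and 2.64-fold in chromium EC10 besides cobalt and PLO. UDP glycosyltransferase A9 (Fcc05569) rose in 4, 2.62-fold in chromium EC50 and 1.20 ± 0.25 on the log2 scale in chromium EC10 besides the field soils, and retinol dehydrogenase 12 (Fcc00270) rose in 4, 2.18-fold in chromium EC50 and 2.57-fold in chromium EC10 besides cobalt. The series 2 control minus the series 1 control was -0.40 for the first of these, -0.39 for the second and 0.38 for the third.

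At EC50, with each metal set against its own control, barium and lead differed in 81 genes (45 higher with barium and 36 higher with lead), barium and cadmium in 37, cadmium and zinc in 2, barium and zinc in 1, cadmium and lead in 1, and lead and zinc in 0 by limma (171 at an unadjusted p under 0.05). Cobalt and chromium differed in 775.

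The strongest loadings on the common axis within groups were those of Fcc05079 (-1.35), Fcc06283 (-0.999) and cephalosporin hydroxylase (Fcc00074, -0.91), a gene of beta-lactam synthesis. On the axis that held 14.9% of the variance within groups, the 6 cuticle and chitin genes had a mean size of loading of 0.311, above the 95th percentile of 0.182 of matched lists. No other list was tested on that axis, and none on the axis with 15.8% of the variance. The value thus does not show that the axis is particular to cuticle genes.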
